A study of Mus musculus with 34 samples.

How the data were processed

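Per the labels, RNA was extracted with Trizol from 3 Peg3 KO lines and 4 WT lines of mouse TS-Rs26 trophoblast stem cells, and libraries were made with an Ultra II Directional RNA kit. The lines were sampled in the stem state and at days 2 and 4, and each of the 21 libraries was sequenced in 2 lanes. The change of culture behind days 2 and 4 is not stated in the labels used here. The deposited files hold raw counts per gene for each lane, and a series table holds counts summed over lanes by the authors. The labels name STAR, Bowtie2, SAMtools, HTSeq and the builds GRCm38 and mm10, with no versions, and the strand setting is not given in the sources used here. The 13 samples of methylated DNA immunoprecipitation and input (4 KO, 6 WT and 3 inputs) are not analysed here.

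The lane counts of each library were added. The sums equalled the authors' series table in every cell (0 differing values). The files hold 55487 genes, of which 55141 had a symbol and 346 did not. The lanes of a library differed by little more than counting error (chi-squared per gene 1.085 to 1.156, genes of 10 reads or more), while 27 pairs of replicate libraries differed by 11.69 to 320.32. Depth, in units of 1e6 counts, was 19.3 to 56.1 (median 32.1), mitochondrial genes took 1.658% to 2.154% of counts and no gene took over 1.111%.

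Groups were taken from genotype and day (6 groups). Genes were filtered with filterByExpr, which left 16137 for all libraries and 17346 for the sums per line. Counts were scaled by TMM (factors 0.968 to 1.038). They were fitted with edgeR 4.0.16 in R 4.3.3 by a robust quasi-likelihood model with 1 mean per group. The 15 residual degrees of freedom are not independent, since each line was sampled at every day and its libraries correlate across days. The main p-values do not account for this. KO was compared with WT at each day and for counts summed over days per line, days 2 and 4 with day 0 in each genotype, and the change between genotypes by interactions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of single genes are from edgeR unless DESeq2 or limma is named. Fold changes are log2 values with SE, and means are CPM (counts per 1e6 counts) with SD.

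Of the gene lists, 28 were fixed before the data were examined, as were the tests, the groups and the first set of alternatives. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a correlation between genes of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a contrast. Counts of called members are given over all genes and adjusted over the list alone. Named genes followed a rule. Peg3 came first in every library. For each comparison of genotypes or interaction the 8 largest rises and falls among called genes with a mean log2 CPM of 0 or more were named, and for KO against WT the groups had also to be without overlap. For each day contrast the minimum was 3. Up to 4 called members of each list with the smallest adjusted p were added, and for the sums the 10 genes with the smallest p. Predicted and clone names were left out (Gm plus digits, Rik, LOC, AC, AL or BC plus digits, and -ps). Group means of Cdx2, Eomes, Sox2, Syna and Prl3d1 that fall outside the rule were added for their known roles after their values were seen.

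Where a group had 1 to 3 counts over its libraries, the ratio of rates is given with a 95% exact interval, and at 0 counts a bound against a floor of 3 counts over the group. These intervals cover counting error only and not the spread between lines. Medians of lists with members at 0 are also given with those members at their bound. Chromosome medians were taken over 8029 genes with a mean log2 CPM of 4 or more, as differences from the WT mean of the same day, averaged over days. Principal components used the 1000 most variable genes.

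Alternatives were RLE and upper-quartile scaling, no filter on low counts, a mean log2 CPM of at least 1, DESeq2 1.42.0, limma-voom, each lane alone, the authors' summed table, a log2 fold change of at least 1, only the libraries of the groups compared, each line left out and a replicate block. The block was the replicate number for KO against WT, where it pairs no samples, and the line for day contrasts and interactions. Libraries of one line at other days correlated with r of 0.194 to 0.624, and KO and WT libraries of the same number with r of -0.176 to 0.169. Offsets for chromosome medians, the list tests without KO44, and the line block without KO44 were added after the data were seen. The real groups were compared with all 35 splits of the 7 lines, or for the day contrasts with the splits of the libraries that part both libraries of every line (8 in WT and 4 in KO).

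The pipeline was tested on simulated data of 16137 genes. For KO against WT at day 0 it recovered 17.9% of changes of 1.5-fold, 62.7% of 2-fold and 93.9% of 4-fold changes, with 3 false calls of 119. For day 4 the recoveries were 10.4%, 47.8% and 90.9% with 6 false calls of 105, and for the interaction at day 4 they were 4.5%, 29.9% and 84.8% with 2 of 81. A raised list was called by camera (adjusted p = 2.65e-25, or 9.04e-07 with an estimated correlation) with 0 of 27 unchanged lists called. In these simulations each gene and library was drawn independently, with no correlation between genes and no line effect. The false calls and list results under such correlation were therefore not checked. Changed genes and lists were drawn from genes with a mean log2 CPM above 2, so recovery at lower expression was not checked. A simulated loss to 0.75 of chromosome 5 in a line gave a median of -0.39. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.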

Results

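RNA was sequenced from 7 lines of mouse trophoblast stem cells, the multipotent cells of the early placenta that grow in culture with fibroblast growth factor and heparin. The parental line is TS-Rs26. In 3 lines the imprinted gene Peg3, a zinc finger gene expressed from the paternal allele, had been knocked out (KO19, KO34 and KO44), and 4 lines were wild type (WT6, WT7, WT9 and WT17). Each line was sampled in the stem state (day 0) and at days 2 and 4, which gave 21 libraries in 6 groups, with n = 3 for KO and n = 4 for WT at each day. The same 7 lines were therefore measured at all 3 days. Library totals (mean ± SD, in units of 1e6 counts) were 30.6 ± 2.26 in KO and 32.5 ± 1.38 in WT at day 0. They were 30.7 ± 7.37 and 24.6 ± 5.45 at day 2, and 42.7 ± 12.6 and 37.8 ± 8.89 at day 4, with a range of 19.3 to 56.1 over all libraries. Between 19076 and 22938 genes were detected per library, and 16137 genes were tested. The study also holds 13 samples of methylated DNA immunoprecipitation and input, which are not analysed here.

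Peg3 separated the genotypes in every library. Peg3 (ENSMUSG00000002265, GRCm38 chromosome 7, 6703892 to 6730462) encodes a DNA-binding protein of the placenta and brain. At day 0 it had 41.4, 40.2 and 37.3 CPM (counts per 1e6 counts of the library) in KO19, KO34 and KO44, and 286, 264, 444 and 235 CPM in WT6, WT7, WT9 and WT17. At day 2 the KO libraries had 77.3, 71.2 and 34.6 CPM and the WT libraries 476, 432, 931 and 438 CPM. At day 4 the values were 104, 141 and 98.1 CPM in KO and 765, 690, 1369 and 817 CPM in WT. The group means were 39.6 ± 2.09 and 307 ± 93.3 CPM at day 0, 61.0 ± 23.1 and 569 ± 242 CPM at day 2, and 114 ± 23.1 and 910 ± 310 CPM at day 4 (SD). The log2 difference was -2.96 (SE 0.35, adjusted p = 0.000355) at day 0, -3.22 (adjusted p = 0.00023) at day 2 and -2.99 (adjusted p = 8.05e-05) at day 4. It passed without any single line, with adjusted p up to 0.0045. Peg3 rose from day 0 to day 4 by log2 1.57 in WT (adjusted p = 0.000174) and by 1.53 in KO (adjusted p = 0.00128).

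**Figure D1:**
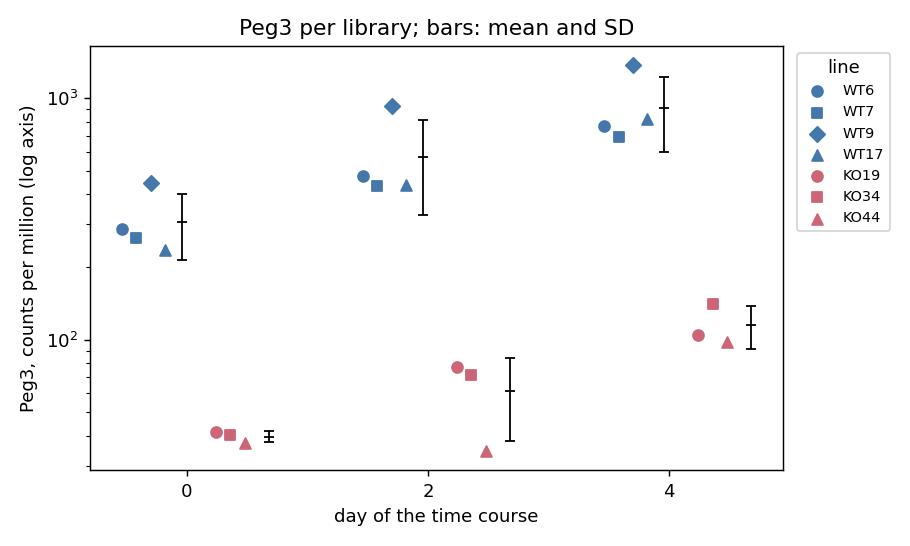
Peg3 in CPM (log axis) in each library by day, with 1 symbol per line and bars at the mean and SD of each group. The highest KO library had 141 CPM and the lowest WT library 235 CPM.

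Peg3's neighbours on chromosome 7 were lower in KO too. Usp29 (ENSMUSG00000051527, 6730559 to 6967220), which shares its promoter region with Peg3, had 4.14 ± 2.49 CPM in KO and 12.7 ± 6.84 CPM in WT at day 4 (log2 -1.61, SE 0.49, adjusted p = 0.0303). That call held only without KO34, and adjusted p rose up to 0.116 without any other single line. Zim1 (ENSMUSG00000002266, 6674444 to 6696540), an imprinted zinc finger gene, had 15.8 ± 11.3 and 70.0 ± 21.5 CPM (log2 -2.14, SE 0.41, adjusted p = 0.00236). Of the 3 measured genes of the domain, which include Peg3 itself, 1 (Peg3) was lower at day 0, 2 at day 2 and 3 at day 4. All 3 were lower at each day when adjusted over the list alone. That adjustment covers 3 genes, with Peg3 fixed by the knockout to be lower, so it corrects little for Usp29 and Zim1. The median gene of chromosome 7 was at log2 -0.55 in KO44. With the chromosome medians of each line removed, the log2 differences of Peg3, Usp29 and Zim1 at day 4 were -2.81, -1.46 and -2.07. The list test gave adjusted p = 5.19e-05 at day 0 (0.0436 with an estimated correlation), 8.59e-05 at day 2 (0.0867) and 0.00076 at day 4 (0.192). The fall of Peg3, a member of the list, was fixed by the knockout, so this test is no separate support for its neighbours.

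Day was the main axis of variation, and the genotypes parted on the third component. Over the 1000 most variable genes the first principal component held 65.6% of the variance and ordered the libraries by day. The third component (9.6%) had scores from 3.85 to 57.64 in the KO libraries and from -21.35 to -9.69 in the WT libraries. KO44 stood apart from the other KO lines on it, at 30.49, 45.71 and 57.64 on days 0, 2 and 4. Each of the 21 libraries correlated best, after removal of the group means, with a library of its own line (r across genes 0.194 to 0.624).

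**Figure D2:**
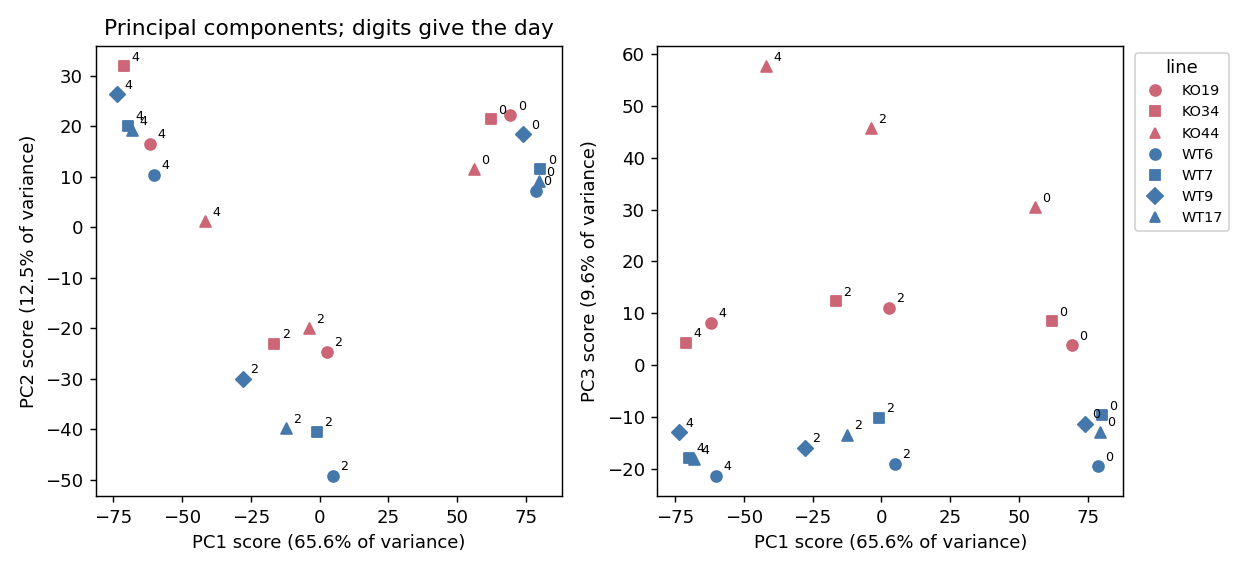
Scores of the 21 libraries on principal components 1 and 2 (left) and 1 and 3 (right), with 1 symbol per line and the day beside each point. Component 3 places all KO libraries above all WT libraries, and KO44 highest at each day.

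Lines differed from each other over whole chromosomes. Among 8029 well expressed genes, the median log2 difference from the WT mean was -0.35 on chromosome 5 in KO19, and -0.36 on chromosome 13 and -0.39 on chromosome 18 in KO34. KO44 showed -0.40 on chromosome 5, -0.55 on chromosome 7, -0.48 on chromosome 13 and 0.25 on chromosome 18. The other 133 pairs of line and chromosome lay between -0.18 and 0.15, and without chromosome 8 between -0.08 and 0.05. Chromosome 8 parted the lines of both genotypes, at every day and in each of 4 parts of the chromosome. Its median was -0.145 in WT6, -0.15 in WT9 and -0.18 in KO44, and 0.15 in WT7, 0.15 in WT17, 0.14 in KO19 and 0.15 in KO34. The WT lines thus differed from each other on chromosome 8 by more than from their mean. At day 0, 54.4% of the 57 genes called on chromosomes 5 and 13 were lower in KO, against 22.7% of the 453 on other chromosomes. With each line's chromosome medians removed the share was 21.7% of 60 calls, a drop that this centring brings about by construction.

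**Figure D3:**
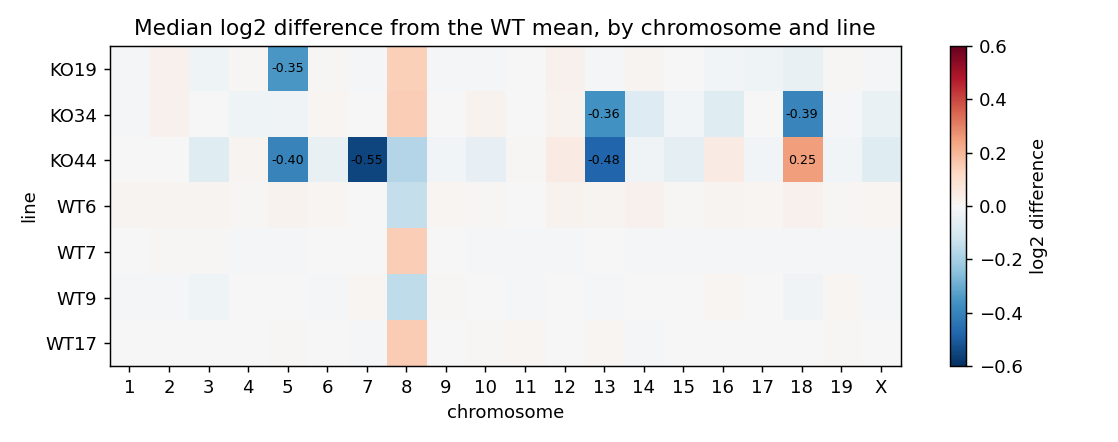
Median log2 difference from the WT mean per line and chromosome, averaged over the 3 days, with values printed where they exceed 0.2 in size. The 7 values of that size lie in KO lines. Chromosome 8 parts the WT lines from each other, at -0.145 in WT6 and -0.15 in WT9 against 0.15 in WT7 and WT17. As the reference is the mean of these WT lines, the gap between them is wider than each value.

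At day 0 the comparison asked what KO lines express differently while still in the stem state. Genes of trophoblast giant cells, the large polyploid cells that invade the uterus and secrete hormones, were higher in KO: 6 of 22 rose and 0 fell. Adjusted over the list alone, 13 rose and 0 fell. Hsd3b6, a steroid enzyme of giant cells, had 2.63 ± 1.86 CPM in KO and 0.101 ± 0.0313 CPM in WT (log2 4.66, SE 0.74, adjusted p = 0.00224). The list's median difference was log2 2.57, or 2.43 with the 3 members at 0 counts in a group set to their bound, with adjusted p = 4.03e-07 (0.0436 with an estimated correlation). Of 99 list results that passed over all contrasts, 5 also passed with an estimated correlation. Without KO44 the median was 2.99 and adjusted p = 1.65e-08 (0.0783 with an estimated correlation). Prl3d1, the placental lactogen that marks giant cells, averaged 11.0 ± 6.74 CPM in KO and 1.25 ± 0.641 CPM in WT. In the prolactin family, a hormone gene cluster on chromosome 13 with near-identical members, 6 of 17 rose and 0 fell (8 and 0 adjusted over the list alone). That list gave adjusted p = 3.05e-05 (0.182 with an estimated correlation). Many members of the giant cell list belong to this family, so the results of these lists are not independent.

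Epithelial genes were also higher in KO at day 0: 11 of 20 rose and 0 fell, and 12 and 0 adjusted over the list alone. Their median was log2 1.13 and adjusted p = 2.65e-10 (0.0243 with an estimated correlation). Krt7, a keratin of simple epithelia, had 482 ± 244 CPM in KO and 89.0 ± 24.6 CPM in WT (log2 2.44, SE 0.27, adjusted p = 0.00021). Grhl2, a transcription factor that maintains epithelia, was higher by log2 1.35 (adjusted p = 0.00171). The mesenchymal intermediate filament gene Vim had 6.65 ± 6.93 CPM in KO and 150 ± 31.0 CPM in WT (log2 -4.50, SE 1.07, adjusted p = 0.0288). Zeb1, a repressor of epithelial genes, had 4.08 ± 4.01 and 28.9 ± 7.07 CPM (log2 -2.82, adjusted p = 0.022). Adjusted p of Vim rose up to 0.125 without KO19 or any single WT line, and that of Zeb1 up to 0.108 without KO19, WT6 or WT17. The wider mesenchymal list went both ways, with 1 of 16 higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.951). The pluripotency factor Klf2 was higher by log2 2.29 (adjusted p = 0.00021) and the stress factor Atf3 by 2.33 (adjusted p = 0.000945).

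The stem cell genes differed little at day 0. Of 18 such genes, 1 was lower and 0 higher (1 lower and 1 higher adjusted over the list alone; adjusted p = 0.711). Cdx2, which specifies trophoblast, had 176 ± 18.4 CPM in KO and 234 ± 33.7 CPM in WT, and Eomes 665 ± 56.7 and 480 ± 98.98 CPM. Dnmt3l, a cofactor of DNA methylation, had 6.51 ± 2.71 CPM in KO and 48.0 ± 26.1 CPM in WT (log2 -2.88, adjusted p = 0.0161). Its adjusted p rose up to 0.0902 without KO34, WT6 or WT17. The DNA methylation list held 1 higher and 2 lower of 19 (1 and 3 adjusted over the list alone; adjusted p = 0.00954, or 0.212 with an estimated correlation). Homeobox genes of the Rhox cluster, an X-linked family of similar sequence, rose in 3 of 10 cases and fell in 0 (7 and 0 adjusted over the list alone; adjusted p = 0.000216, or 0.188). Spongiotrophoblast genes rose in 2 of 10 cases and fell in 0, the same adjusted over the list alone (adjusted p = 0.0488, or 0.182). Hypoxia and glycolysis genes fell in 2 of 20 cases and rose in 0 (7 and 1 adjusted over the list alone; adjusted p = 0.00024, or 0.315). Without KO44, 8 of these 20 fell.

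Some further lists differed between the genotypes at day 0. Targets of p53 rose in 2 of 20 cases and fell in 0 (11 and 0 adjusted over the list alone; adjusted p = 2.84e-06, or 0.213 with an estimated correlation). The 20 S phase genes had 0 single calls by edgeR and a median of log2 -0.33 (adjusted p = 0.00164, or 0.589). The 80 ribosomal protein genes had 0 single calls by edgeR and a median of -0.18 (adjusted p = 0.00193, or 0.755, and 0.41 without KO44). Genes of the unfolded protein and amino acid stress responses rose in 2 of 17 cases and fell in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.0488, or 0.589, and 0.18 without KO44).

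In all, 510 of 16137 genes were called at day 0, of which 376 were higher and 134 lower in KO. Of these calls, 493 had KO and WT libraries that did not overlap. Non-overlap was found in 19.4% of all genes tested, where chance gives 5.7%. At least a doubling or halving in the fitted value was seen for 361 calls. The count was 125 without WT6, 318 without WT7 and 73 without WT17. It was 297 with no low-count filter, 869 with the replicate block and 1084 with DESeq2. Among the largest differences the macrophage growth factor receptor gene Csf1r had 20.4 ± 21.7 CPM in KO and 1.23 ± 0.285 CPM in WT (log2 4.05, adjusted p = 0.0184). KO44 had 45.4 CPM of Csf1r and the other KO lines 7.60 and 8.04, and adjusted p rose up to 0.116 without any single WT line. Plxdc2 was higher by log2 3.62 (adjusted p = 0.0018). The largest falls besides Vim and Peg3 included the kinase-like gene Camkv (log2 -3.50, adjusted p = 0.00286) and the adhesion receptor gene Adgra2 (log2 -3.23, adjusted p = 0.00169). The calls for Plxdc2, Camkv, Adgra2, Hsd3b6, Krt7, Grhl2, Klf2 and Atf3 passed without any single line.

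At day 2 the comparison asked how KO and WT differ as cells leave the stem state. Targets of fibroblast growth factor and its kinase ERK, the signal that maintains trophoblast stem cells, were higher in KO: 8 of 16 rose and 0 fell. Adjusted over the list alone, 9 rose and 1 fell (median log2 1.36; adjusted p = 0.00531, or 0.333 with an estimated correlation). Fosl1, a transcription factor induced by ERK, had 22.4 ± 22.2 CPM in KO and 2.48 ± 0.436 CPM in WT (log2 3.17, SE 0.51, adjusted p = 0.00243). The ERK phosphatase genes Dusp6 and Dusp5 were higher by log2 2.03 (adjusted p = 0.00243) and 2.55 (adjusted p = 0.00314). Dusp4, a phosphatase gene of the same list, went the other way with counts summed over days, where it was lower in KO. Without KO44, 4 of the 16 rose and 0 fell (adjusted p = 0.0386, or 0.364 with an estimated correlation).

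Targets of p53, which responds to DNA damage and other stress, were higher at day 2: 12 of 20 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was log2 1.06 and adjusted p = 6.49e-08 (0.231 with an estimated correlation). Mdm2, which degrades p53, was higher by log2 1.16 (SE 0.21, adjusted p = 0.00444) and the cyclin gene Ccng1 by 1.03 (adjusted p = 0.00504). Inflammatory targets of TNF and NF-kappaB rose in 4 of 15 cases and fell in 0 (11 and 0 adjusted over the list alone; adjusted p = 6.99e-05, or 0.252). Giant cell genes had the highest median of the lists at day 2, at log2 3.28, or 2.70 with 5 members at their bound. In it 9 of 22 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 7.94e-08, or 0.0867). Prl3d1 had 5.27 ± 3.58 CPM in KO and 0.176 ± 0.131 CPM in WT (log2 4.78, SE 0.92, adjusted p = 0.00573). Epithelial genes rose in 8 of 20 cases and fell in 0 (12 and 0 adjusted over the list alone; adjusted p = 2.32e-05, or 0.119), and without KO44 4 of them rose.

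Proliferation and ribosome lists were lower at day 2 as sets, with few single genes called. Of the 20 S phase genes 1 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 4.27e-05, or 0.476 with an estimated correlation). At day 4 2 of them fell and 0 rose (0 and 0 adjusted over the list alone), with a median of log2 0.22 (adjusted p = 0.446, and 0.00496 without KO44). The 80 ribosomal protein genes had 0 single calls by edgeR and a median of log2 -0.31 (adjusted p = 6.49e-08, or 0.637). Genes named Rpl or Rps plus a digit, which are not the same set as this list, took 2.80% of counts in KO44. They took 4.61% in KO19 and 4.72% in KO34, and 4.68% to 5.03% in the WT lines. The 20 G2 and M phase genes had 0 calls by edgeR, over all genes or adjusted over the list alone, with median log2 -0.34 (adjusted p = 0.000238, or 0.587). Of 19 cholesterol synthesis genes 1 rose and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.0029, or 0.587). Collagen and other feeder fibroblast genes rose in 3 of 14 cases and fell in 0, also adjusted over the list alone (adjusted p = 0.0318, or 0.331), and the list gave 0.271 without KO44.

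At day 2, 1268 genes were called, 972 higher and 296 lower, and 1207 of them without overlap between the groups. Non-overlap held for 25.4% of all genes, where chance gives 5.7%. The count was 292 without WT6, 768 without WT7, 757 without WT9, 240 without WT17 and 777 without KO44. It was 716 with only the libraries of the groups compared, 774 with no low-count filter, 844 with limma-voom, 2010 with the replicate block and 2179 with DESeq2. The neuropilin gene Nrp2 was higher by log2 4.93 (SE 0.57, adjusted p = 0.000321) and the lncRNA gene Mirt1 by 5.08 (adjusted p = 0.00291). Psg29, a pregnancy-specific glycoprotein gene, had 103 counts over the KO libraries and 1 over the WT libraries, a rate ratio of 110 (95% interval 19.3 to 4390). The oxidase gene Duox1 had 143 and 3 counts, a ratio of 51.0 (17.1 to 250). The receptor gene Tnfrsf19 was lower by log2 -2.88 (adjusted p = 0.00204) and the matrix gene Tgfbi by -2.96 (adjusted p = 0.0139). The calls for Fosl1, Dusp5, Dusp6, Mdm2, Ccng1, Prl3d1, Nrp2, Mirt1, Psg29, Duox1, Tnfrsf19 and Tgfbi passed without any single line.

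At day 4 the comparison asked how the differentiated cultures differ. Genes of the syncytiotrophoblast and labyrinth, the layers that exchange nutrients with maternal blood, were lower in KO in 5 of 16 cases and higher in 2. The same held adjusted over the list alone (median log2 -0.50; adjusted p = 0.0427, or 0.463 with an estimated correlation). The list gave 0.0827 without KO44. Gjb2, a gap junction gene of the labyrinth, had 35.5 ± 27.8 CPM in KO and 307 ± 106 CPM in WT (log2 -3.11, SE 0.705, adjusted p = 0.00675). The transcription factor gene Tfeb was lower by log2 -1.18 (adjusted p = 0.00139) and Ly6e, needed for syncytin-driven fusion, by -1.83 (adjusted p = 0.00329). The syncytin gene Syna had 29.7 ± 19.9 CPM in KO and 96.5 ± 33.2 CPM in WT. Giant cell genes stayed higher, with 9 of 22 rising and 0 falling (12 and 0 adjusted over the list alone; median log2 1.99; adjusted p = 5.41e-05, or 0.192). Cyp11a1, which makes pregnenolone in giant cells, was higher by log2 3.93 (adjusted p = 0.00257). The prolactin family, which shares many members with the giant cell list, rose in 7 of 17 cases and fell in 0 (8 and 0 adjusted over the list alone, adjusted p = 0.00896, or 0.463).

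Genes of the unfolded protein and amino acid stress responses fell in 6 of 17 cases and rose in 0 at day 4 (9 and 0 adjusted over the list alone, median log2 -0.73). That list gave adjusted p = 0.000693, or 0.463 with an estimated correlation. At day 0 the same list was higher, a call that was lost with an estimated correlation and without KO44. Asns, which makes asparagine, was lower by log2 -1.43 (adjusted p = 0.012), with adjusted p up to 0.067 without KO19 or KO44. Cytosolic ribosomal protein genes, which encode the protein part of the ribosome, fell in 23 of 80 cases and rose in 0 (44 and 0 adjusted over the list alone; median log2 -0.60). The set gave adjusted p = 1.02e-15, or 0.463 with an estimated correlation. Rps4x fell by 0.85 on the log2 scale (adjusted p = 0.00215) and Rpl17 by 0.77 (adjusted p = 0.0012). A share of counts was taken over genes named Rpl or Rps plus a digit, which is not the same set as the list. It leaves out Rplp0, Rplp1, Rplp2 and Rpsa and takes in kinase genes such as Rps6ka6. This share was 3.12 ± 1.08% in KO and 4.70 ± 0.104% in WT at day 4. It was 5.11 ± 0.874% and 5.59 ± 0.317% at day 0, and 4.04 ± 1.08% and 4.92 ± 0.163% at day 2. KO44 had the lowest share at each day, with 4.10%, 2.80% and 1.87%. Without KO44 the list's median at day 4 was -0.31, and 48 of the 80 fell and 1 rose.

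**Figure D4:**
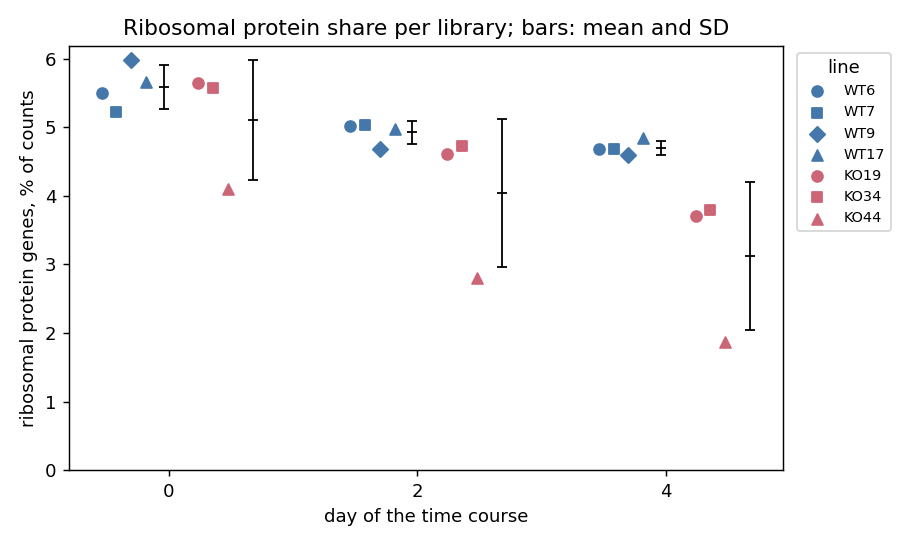
Percentage of counts on genes named Rpl or Rps plus a digit in each library by day. Each line has 1 symbol, and bars lie at the mean and SD of each group. At day 4 the KO libraries lie between 1.87% and 3.79% and the WT libraries between 4.59% and 4.84%.

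Stress and inflammatory targets remained higher at day 4. Targets of p53 rose in 8 of 20 cases and fell in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.0282, or 0.669 with an estimated correlation). TNF and NF-kappaB targets rose in 6 of 15 cases and fell in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.0252, or 0.463). Without KO44 the adjusted p was 0.168 for the p53 list and 0.223 for the TNF list. Nfkb1, a subunit of NF-kappaB, was higher by log2 2.82 (adjusted p = 0.00831), but by 0.44 without KO44, where adjusted p was 0.282, and its adjusted p was 0.0524 without WT17. Feeder fibroblast genes rose in 5 of 14 cases and fell in 0, also adjusted over the list alone (adjusted p = 0.0452, or 0.463, and 0.0966 without KO44). The Rhox cluster had 4 of 10 higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0282, or 0.463). Mitochondrially encoded genes rose in 5 of 14 cases and fell in 0, also adjusted over the list alone (adjusted p = 0.0416, or 0.463). The lists that did not pass at day 4 included maternally expressed imprinted genes (5 of 22 higher, 0 lower; adjusted p = 0.185) and paternally expressed ones (3 of 19 higher, 1 lower; adjusted p = 0.381). Adjusted over the list alone the imprinted lists had 8 higher and 2 lower, and 4 higher and 1 lower. Extraembryonic endoderm genes had 3 of 10 higher and 1 lower (adjusted p = 0.316) and embryonic stem cell genes 0 higher and 1 of 11 lower (adjusted p = 0.176), the same adjusted over the list alone.

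At day 4, 2914 genes were called, 1680 higher and 1234 lower, and 2403 of them without overlap between the groups. With limma-voom 2941 were called, 1444 higher and 1497 lower, so the excess of higher calls depended on the tool. Non-overlap held for 25.3% of all genes, where chance gives 5.7%. The edgeR count was 1352 without WT6, 1609 without WT7, 1184 without WT17 and 732 (440 higher and 292 lower) with only the libraries of the groups compared. The growth factor gene Fgf13 had 887 counts over the KO libraries and 2 over the WT libraries, a rate ratio of 539 (95% interval 149 to 4460). Lhfpl5 had 0 counts over the KO libraries and 119 over the WT libraries, at least 32.6-fold lower in KO against a floor of 3 counts over the group. The membrane gene Mal was higher by log2 5.66 (adjusted p = 0.000262). Gfra3, a neurotrophic factor receptor gene, was lower by log2 -4.45 (adjusted p = 0.000176) and Adgra2 by -4.01 (adjusted p = 0.000126). Vim stayed low, with 3.24 ± 4.08 CPM in KO and 57.0 ± 11.5 CPM in WT (log2 -4.19, adjusted p = 0.0126, and up to 0.0624 without KO19 or WT17). The calls for Gjb2, Tfeb, Ly6e, Cyp11a1, Rps4x, Rpl17, Fgf13, Lhfpl5, Mal, Gfra3 and Adgra2 passed without any single line.

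**Figure D5:**
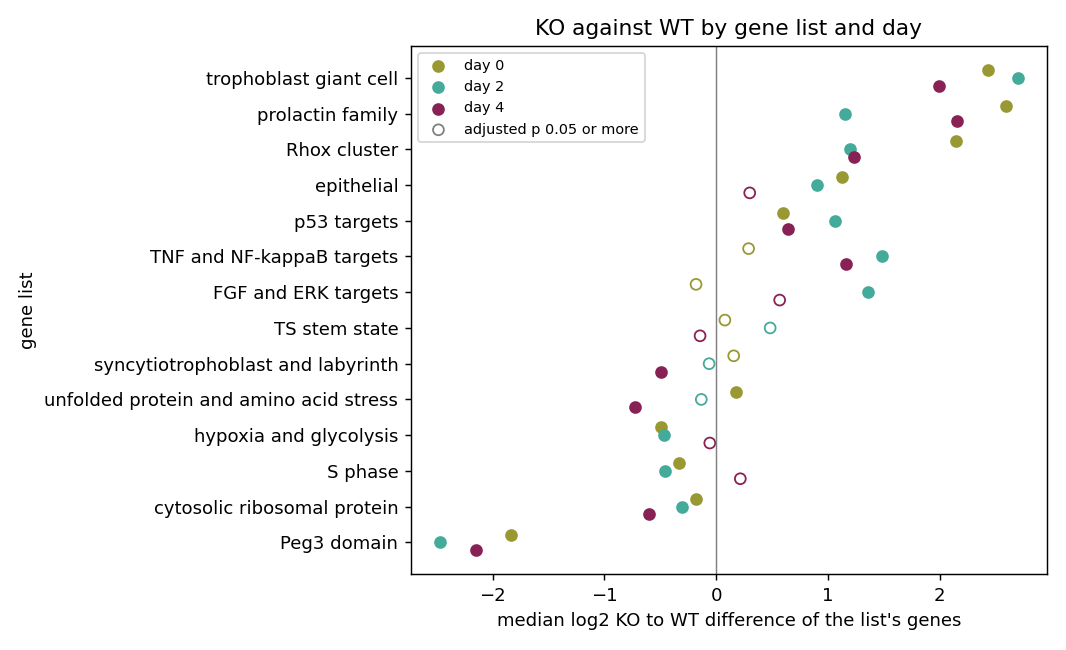
Median log2 KO to WT difference of the genes of 14 lists at each day, with members at 0 counts in a group set to their bound and open symbols where adjusted p was 0.05 or more. The trophoblast giant cell list lies highest and the Peg3 domain, which includes Peg3 itself, lowest at day 2.

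Calls were shared between days. Of the genes higher in KO, 114 were called at all 3 days, against 2.36 if the lists were independent. Of the genes lower in KO, 31 were called at all 3 days, against 0.19. The same lines were sampled at each day, so the lists are not independent. In the 34 other splits of the 7 lines into 3 and 4, at most 1 gene was called the same way at all 3 days, against 145 in the real split. With counts summed over the days for each line, 655 of 17346 genes were called, 456 higher and 199 lower. This count was 0 without WT6 or WT17, 31 without WT7, 3 without WT9 and 1189 without KO34. With the replicate block edgeR called 0 genes, so all 10 genes named for the sums lost their call. That block pairs no samples and leaves few residual degrees of freedom among the 7 sums. Without a block 4455 genes had an unadjusted p under 0.05 by edgeR, and DESeq2 called 2663. Peg3 was among the 10 genes with the smallest adjusted p (log2 -2.98, SE 0.30, adjusted p = 0.0236). Its adjusted p rose up to 0.0962 without WT6 or WT17. The adhesion plaque gene Pkp3 was higher by log2 1.92 (adjusted p = 0.0193) and the phosphatase gene Dusp4 lower by -1.26 (adjusted p = 0.0236). Adjusted p of both rose up to 0.0962 without WT6, WT9 or WT17. Dusp4 is a member of the list of fibroblast growth factor and ERK targets, which as a set was higher in KO at day 2.

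The course from day 0 to day 2 in WT asked which genes change when the cells leave the stem state. Targets of fibroblast growth factor and ERK fell in 14 of 16 cases and rose in 0, also adjusted over the list alone. Their median was log2 -4.01 and adjusted p = 1.36e-13 (0.0229 with an estimated correlation). Dusp6 was lower by log2 -7.92 (adjusted p = 3.12e-11). Stem cell genes fell in 11 of 18 cases and rose in 3, also adjusted over the list alone (adjusted p = 0.000155, or 0.156 with an estimated correlation). Sox2, a core factor of the stem state, was lower by log2 -9.64 (adjusted p = 3.95e-08). Nr0b1 had 14576 counts over the day 0 libraries and 2 over those of day 2, a rate ratio of 5540 (95% interval 1530 to 45700). Syncytiotrophoblast and labyrinth genes rose in 10 of 16 cases and fell in 2, also adjusted over the list alone (adjusted p = 0.00306, or 0.231). Pparg, which drives labyrinth formation, was higher by log2 5.36 (adjusted p = 9.06e-07) and the spongiotrophoblast factor Ascl2 by 7.16 (adjusted p = 1.07e-05). In all 5375 genes were called, 2551 higher and 2824 lower.

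From day 0 to day 4 in WT, placental and interferon genes were higher and cell cycle genes lower. Syncytiotrophoblast and labyrinth genes rose in 12 of 16 cases and fell in 2, also adjusted over the list alone (adjusted p = 0.000268, or 0.239 with an estimated correlation). Syna had 0.108 CPM at day 0 and 96.5 CPM at day 4 (log2 9.75, adjusted p = 1.57e-09). Interferon response genes, which block viral replication, rose in 14 of 15 cases and fell in 0, also adjusted over the list alone (median log2 3.21; adjusted p = 1.55e-05, or 0.289). Stat1, a mediator of interferon signals, was higher by log2 3.21 (adjusted p = 5.09e-08). G2 and M phase genes fell in 19 of 20 cases and S phase genes in 17 of 20, with 0 rising in either list and the same counts adjusted over the list alone. Their adjusted p was 3.77e-06 (0.395 with an estimated correlation) and 4.92e-05 (0.395). Cdk1, the mitotic kinase, was lower by log2 -1.59 (adjusted p = 5.22e-07). Cholesterol synthesis genes fell in 16 of 19 cases and rose in 2, also adjusted over the list alone (adjusted p = 0.00259, or 0.43). Giant cell genes rose in 11 of 22 cases and fell in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.0639).

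Imprinted genes changed in both directions over the same 4 days in WT. Paternally expressed imprinted genes rose in 7 of 19 cases and fell in 3, and maternally expressed ones rose in 10 of 22 and fell in 8, also adjusted over the list alone. Their adjusted p was 0.218 and 0.366. At day 2 the paternally expressed list was higher, with 10 of 19 rising and 1 falling in WT (adjusted p = 0.0237, or 0.231 with an estimated correlation) and 3 rising and 0 falling in KO (adjusted p = 0.0194, or 0.255), also adjusted over the list alone. Peg10, needed for placenta formation, was higher by log2 3.62 (adjusted p = 6.94e-08), and Mest lower by -4.75 (adjusted p = 6.16e-07). The growth inhibitor gene Cdkn1c was higher by log2 4.50 (adjusted p = 7.6e-09). Germline genes that DNA methylation silences fell in 7 of 14 cases and rose in 0, also adjusted over the list alone (adjusted p = 0.038, or 0.395 with an estimated correlation). Of 24 replication-dependent histone genes, near-identical in sequence, 6 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.504). In all 9775 of 16137 genes were called, 4696 higher and 5079 lower. With RLE scaling most calls were higher (4948 against 4822). The median gene lay at log2 -0.08 with the main scaling, -0.145 with upper-quartile scaling and -0.029 with RLE, and in KO at -0.03, -0.102 and 0.029.

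The KO lines followed most of the same course. From day 0 to day 2, 3210 genes were called in KO, 1644 higher and 1566 lower, and 5508 with the line as a block. The count was 1838 without KO19 and 1809 without KO34. Lower calls were more numerous with upper-quartile scaling (1520 higher and 1707 lower), limma-voom (1497 and 1623) and the line block (2671 and 2837). The same held with only the libraries of the groups compared (726 and 844). From day 0 to day 4, 8173 genes were called, 4047 higher and 4126 lower. The balance turned with the scaling, to 4343 and 3793 with RLE and 3687 and 4674 with upper-quartile scaling, and the count was 4618 with only the libraries of the groups compared. Of the genes called in WT, 97.5% at day 2 and 95.2% at day 4 had the same sign of change in KO. The correlation of the changes was r = 0.839 at day 2 and 0.893 at day 4 across genes, which are not independent replicates. Targets of fibroblast growth factor and ERK fell in 12 of 16 cases by day 2 and rose in 0, also adjusted over the list alone (adjusted p = 2.5e-13, or 0.0249 with an estimated correlation). Stem cell genes fell in 13 of 18 cases by day 4 and rose in 2, also adjusted over the list alone (adjusted p = 2.95e-05, or 0.252). Sox2 had 173 ± 44.2 CPM at day 0 and 0.112 CPM at day 4 in KO, and 242 ± 57.2 and 0.223 CPM in WT. Ribosomal protein genes fell in 46 of 80 cases by day 4 in KO and rose in 0 (60 and 0 adjusted over the list alone; adjusted p = 1.17e-07, or 0.496). In WT 15 of them fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 0.0405, or 0.775).

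Whether the course itself differed between genotypes was tested by the interaction. From day 0 to day 2 the interaction had 0 genes called by edgeR, with 916 at an unadjusted p under 0.05. DESeq2 called 54 genes, limma-voom 0, and edgeR with the line as a block 67. The list of fibroblast growth factor and ERK targets had 0 genes called over all genes by edgeR and 6 more positive in KO adjusted over the list alone (median log2 1.38; adjusted p = 4.11e-05, or 0.302 with an estimated correlation). From day 0 to day 4, 276 genes were called, 124 with a more positive and 152 with a more negative change in KO, and 1493 with the line as a block. The count was 28 without WT6, 71 without WT7, 21 without WT17, 123 without KO19 and 417 without KO44. Atf3, a stress-induced factor, was higher at day 4 by log2 4.92 in WT and by 2.28 in KO, an interaction of -2.64 (SE 0.44, adjusted p = 0.00617). Its adjusted p was 0.0624 without WT17. Klf2 had an interaction of -2.55 (adjusted p = 0.00279), Epb41l4b 3.72 (adjusted p = 0.0032) and Sept6 2.83 (adjusted p = 0.00391), and all 3 calls passed without any single line. Atf3 and Klf2 were already higher in KO than in WT at day 0. Their negative interactions include that day 0 difference and do not by themselves show lower expression in KO at day 4. In the unfolded protein and amino acid stress list 3 of 17 genes had a more negative change in KO and 0 a more positive one (6 and 0 adjusted over the list alone; adjusted p = 2.64e-07, or 0.197 with an estimated correlation). The epithelial list had 1 of 20 more negative and 0 more positive (4 and 0 adjusted over the list alone; adjusted p = 1.07e-05, or 0.197). Ribosomal protein genes had 0 single calls by edgeR in this contrast and a median of -0.41 (adjusted p = 2.42e-08, or 0.703), and 38 of 80 were more negative with the line as a block. S phase genes also had 0 single calls by edgeR and a median of 0.46 (adjusted p = 0.00189, or 0.703), and 4 of 20 were more positive with the line as a block. For Peg3 the interaction was -0.27 at day 2 (adjusted p = 1) and -0.04 at day 4 (adjusted p = 0.986).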

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

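The tests of normalization, of Peg3 loss common to the KO lines, of copy number, of sequencing depth, of separate handling and of line KO44 alone were chosen after the result was seen.

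Peg3 in WT9 stood far from the other WT lines at day 2, at 931.3 CPM where the others lay between 431.7 and 475.9 CPM. WT9 also had the highest Peg3 at day 0 (444 CPM, the others 235 to 286) and at day 4 (1369 CPM, the others 690 to 817), so the higher level belongs to the line at all 3 days. Among 31 sets of WT values tested, 1 stood out in this way, and chance does so in about 1 in 20 groups.

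The change from day 0 to day 4 differed between genotypes by the interaction test for 276 genes. The log2 interaction was more positive in KO for Htra3 (5.08), Ankrd35 (3.99), Epb41l4b (3.72), Oas3 (3.41), Endou (3.15), Nlrc3 (2.95), Sept6 (2.83), Gfra4 (2.825) and Hk2 (1.25). It was more negative for Stra6 (-4.635), Avil (-4.42), Tubb4a (-4.28), Klk7 (-4.06), Gfra3 (-3.67), Bcl6 (-3.56), Trim46 (-3.43) and Kcnf1 (-3.21). Smaller negative values were found for Atf3 (-2.64), Klf2 (-2.55), Ovol2 (-2.12), Vegfa (-2.05), Klf4 (-1.73), Sesn2 (-1.71), Sgce (-1.51), Cldn3 (-1.09), Sqle (-1.02) and Hspa5 (-0.76). Adjusted p lay between 0.00279 and 0.0482. Only Epb41l4b, Klf2 and Sept6 among these passed without each single line, and the count was 28 without WT6, 71 without WT7, 21 without WT17, 123 without KO19 and 417 without KO44. Atf3 and Klf2 were already higher in KO at day 0, so their negative values do not by themselves mean lower expression at day 4.

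For the counts of KO against WT given next, the 7 lines were split in all 35 ways, and only the real split reached the count. Chance is argued against at a share of 0.029, the smallest that 35 splits allow, but is not excluded. These counts come from the same lines and are not independent. The other splits mix KO and WT lines in at least 1 group, so a genotype difference adds to the spread there. The real count at day 0 was 510 and the highest of the other splits 27, at day 2 they were 1268 and 2, and at day 4 2914 and 293. The sums gave 655 and 1, the interaction at day 4 276 and 1, and the genes called the same way at all 3 days 145 and 1. For the interaction at day 2 the splits decide nothing, since the real count was 0 by edgeR and all 35 splits gave 0. That count had 916 genes at an unadjusted p under 0.05, and was 54 by DESeq2, 0 by limma-voom and 67 by edgeR with the line as a block, for which no splits were run. For the day contrasts the libraries pair by line, and the splits that part all pairs are too few for a share under 0.05. In WT there are 8 of them, with 5375 against 0 at day 2 and 9775 against 0 at day 4, and in KO 4, with 3210 against 0 and 8173 against 3. The other splits keep both libraries of at least 1 line in a group, and in WT their highest count was 1, at day 2.

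The first pattern weighed was the 7 shifts of whole chromosomes over 0.2 in size from the WT mean, which all lie in KO lines. Chromosome 5 was lowered in KO19 and KO44, and chromosome 13 in KO34 and KO44. Chromosome 18 was lowered in KO34 and raised in KO44, and chromosome 7 was lowered in KO44 only. As no WT line had a shift of this size, these shifts are not separate from genotype in KO against WT. The shift of chromosome 8, from -0.18 to 0.15 over lines of both genotypes, was not part of these tests. On it WT lines lie on both sides of their mean, so they differ from each other by more than these values. Normalization of a library would move all chromosomes alike, but the least lowered of chromosomes 5, 7 and 13 in KO44 lay at -0.38 against the median of its chromosomes. Regulation by loss of Peg3 common to the KO lines would need the shifts in all KO lines, and on 4 of 4 chromosomes at least 1 KO line was near the WT mean or of the opposite sign. Changed copy number in the shifted lines may explain the shifts, since each of 4 equal parts of a shifted chromosome, and each day, moved the same way, by at least 0.151. No DNA was analysed here, so copy number was not measured.

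The second pattern was that KO44 stood apart from the other lines. Sequencing depth is argued against, as 0 of the KO44 libraries had a total outside the range of the others over all days, although within days KO44 was the deepest at day 2 (35.4 against 19.3 to 34.5, in 1e6 counts) and the shallowest at day 4 (31.2 against 31.7 to 56.1). Cells of another type stay open, since the medians of 0.291, -0.225 and -0.187 of feeder, embryonic stem and endoderm lists lie below the bound of 1 set before, but members went both ways (interquartile range -0.1 to 1.107 for feeder genes) and no other types were tested. Separate handling of the KO44 libraries cannot be told apart from a property of the line, because KO44 is the only line (1) whose titles have their form. A biological property of that line stays open as untested.

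The third pattern was the higher giant cell genes in KO at day 0. Line KO44 alone is argued against, since the median without it was 2.99. Chromosome medians lay between -0.55 and 0.25, far from the list's median of 2.57 with all lines. A shift of a gene's own chromosome is thus too small to account for that median. With chromosome offsets 100% of the 6 called members stayed called, but offsets of this size could hardly have removed such calls. Effects of a shifted chromosome on genes elsewhere were not tested. More cells on the way to the day 4 state in KO cultures at day 0 is a candidate explanation. The 807 genes that rose most from day 2 to day 4 in WT had a median log2 KO to WT difference of 0.521 at day 0, just over the bound of 0.5 set before. Their interquartile range was -0.149 to 1.563 and 59 were called higher and 2 lower, so a direct effect of Peg3 loss on these genes stays open too.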

How the results depend on the processing

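Offsets for chromosome medians, the list tests without KO44, and the line block without KO44 were chosen after the data were seen.

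With RLE or upper-quartile scaling, each lane alone, a mean log2 CPM of at least 1 or chromosome offsets, every count of called genes stayed within 1.5 times the main value. The authors' summed table equals the main counts in every cell, so its numbers of called genes were the same by construction. No named gene reversed under any setting. At day 0, of 49 named KO against WT genes 48 stayed called with chromosome offsets, 36 with limma-voom, 30 with no low-count filter and 9 without WT17. At day 4, of 104, 101 stayed with offsets, 85 with no low-count filter and 55 without WT17, and 43 of 97 with only the libraries of the groups compared.

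No low-count filter gave 297 genes at day 0, 774 at day 2 and 136 for the interaction at day 4. DESeq2 gave 1084 and 2179 at days 0 and 2, 2663 for the sums, and 54 and 821 for the interactions at days 2 and 4. Limma-voom gave 844 at day 2. The replicate block gave 869 and 2010 at days 0 and 2, 0 for the sums by edgeR, where 4455 genes had an unadjusted p under 0.05 without a block and DESeq2 called 2663, 5508 for KO day 2, and 67 and 1493 for the interactions. Only the libraries of the groups compared gave 716 at day 2, 732 at day 4, 1570 and 4618 for the KO course, and 7 and 126 for the interactions. For the sums the replicate block leaves few residual degrees of freedom. For all these settings the cause was not tested.

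A log2 fold change of at least 1, which by construction keeps fewer genes, gave 805 at day 2, 1368 at day 4, 414 for the sums, 3027 and 5777 for the WT course, 1876 and 4881 for the KO course and 182 for the interaction at day 4. The line block without KO44 gave 8169 for WT day 2, 4862 for KO day 2, and 47 and 1378 for the interactions.

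Leaving out each line in turn gave 73 to 594 genes at day 0, 240 to 1732 at day 2, 1184 to 3621 at day 4, 0 to 1189 for the sums by edgeR, 1809 to 3609 for KO day 2 and 21 to 417 for the interaction at day 4.

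Of 99 list results that passed, 5 did so with an estimated correlation. Of the 99, 73 were kept in direction with fry (103 passed), 93 with a block (106) and 83 without KO44 (104). Without KO44 the G2 and M phase list at day 4 (adjusted p = 0.942 with all lines) passed as higher (0.00922, other settings 0.748 to 0.981). So did the hypoxia and glycolysis list in the interaction at day 2 (0.858 with all lines, 0.0132 without KO44, other settings 0.96 to 0.983). Depth limits genes near 0 counts, whose ratios are given as bounds or intervals.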

Other observations

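The test of Y loss was chosen after the result was seen.

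The DNA methylation list as a whole had no direction from day 0 to day 4, with 6 of 19 higher and 8 lower in WT (7 and 8 adjusted over the list alone; adjusted p = 0.581). In KO 7 were higher and 7 lower (8 and 7 adjusted over the list alone; adjusted p = 0.953). Among its members, Dnmt3a, a methyltransferase that sets new methylation, was higher at day 4 by log2 2.57 in WT (adjusted p = 1.64e-08) and 2.99 in KO (adjusted p = 7.39e-08). Dnmt3b, its close relative, was lower by -2.38 (adjusted p = 1.68e-06) and -2.41 (adjusted p = 1.66e-05). Between genotypes at day 4, the cofactor gene Dnmt3l was lower in KO by -2.84 (adjusted p = 0.00508) and Tet2, which oxidises methylated cytosine, higher by 1.06 (adjusted p = 0.00293).

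Rhox12, an X-linked homeobox gene, was higher in KO at each day, by log2 3.00 at day 0 (adjusted p = 0.00674, and 0.0645 without WT17), 3.04 at day 2 (adjusted p = 0.00482) and 2.72 at day 4 (adjusted p = 0.00113). Of 19 cholesterol synthesis genes, 4 were higher and 1 lower in KO at day 4, also adjusted over the list alone (adjusted p = 0.0539, or 0.796 with an estimated correlation). Ldlr was higher by 1.14 (adjusted p = 0.000158) and Sc5d by 0.74 (adjusted p = 0.0013), and Sqle, the lower member, changed by -0.85 (adjusted p = 0.00425).

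Y-linked genes were absent in some lines of these cells. Over Ddx3y, Eif2s3y and Uty, KO44 had 0 counts and WT17 had 1 count over all its libraries, while the other lines had 8770 to 17739. Mean Ddx3y was 94.6 CPM in WT7 and 44.4 to 55.6 CPM in the others that express it. Loss of the Y chromosome in single lines is a candidate explanation for the 2 lines that lack all 3 genes.

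Whether chromosome-wide shifts move calls to the lower side stays open. On chromosomes 5 and 13 at day 0 the share of lower calls dropped by 32.7 points, from 54.4% of 57 calls to 21.7% of 60, when chromosome offsets were entered, but the offsets centre these chromosomes and bring this about by construction.

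A delayed course in KO is a candidate for part of the difference at day 4, which the slopes below cannot decide. Over 8641 genes the slope of the change to day 4 on the mean change in WT9 and WT17 was 0.838 in KO19, 0.863 in KO34 and 0.649 in KO44, all under the bound of 0.9 set before. The slopes of WT9 and WT17 average 1 by construction and are no comparison for these. The change was measured from day 0, so KO cultures nearer the day 4 state at day 0 would also give slopes under 0.9. That candidate was raised above for the giant cell genes, and the slopes cannot tell it from a delay. A smaller change in the same genes for other reasons, or a spread of this size between WT lines, would give such slopes too, and was not tested.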
